A study of Homo sapiens with 4 samples.

How the data were processed

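Total RNA of 4 cultures was measured on 1-colour (Cy3) Agilent expression arrays, 1 array per culture. The cultures were the human lung cancer lines H1975 and SK-MES-1, each kept for 24 h at 20% O2 or at 50% O2. Groups were taken from the sample titles, with 1 array in each of the 4 groups. Cy3-labelled cRNA was made with a low-input amplification kit, per the labels' protocols. All 4 arrays lay on 1 slide and were read in 1 scan, per the file headers, so no slide or scan effect could be estimated and none separates the groups.

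The authors deposited the scanner output of each array, in which every spot has an intensity on a linear scale. Per the file headers, the spots were read with Agilent Feature Extraction 11.5.1.1, whereas the submitters' processing notes give version 10.10.1.1. The intensity used here, per the file headers, is the processed signal, from which the scanner software had subtracted background and which is not normalized between arrays. A second deposited table holds the same intensity rounded to 3 significant digits. Its values lay within 0.497% of the processed signal of the same spot on every array, so its scale is linear, it is neither centred nor turned in direction, and its column medians were 21.1, 21.7, 27.3 and 29.3 for H1975 at 20% and 50% O2 and SK-MES-1 at 20% and 50% O2. The genome build in the headers is an older one than that of the gene table used for names, so no coordinates are given.

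Each array held 62976 spots, of which 58717 were not controls, for 50599 probes. Control spots and spots with an outlier flag (251, 238, 216 and 258 on the 4 arrays in the order above) were left out. No spot was saturated. The log2 processed signals of a probe's spots were averaged, and the array's 75th percentile over all noncontrol probes was subtracted. Every difference below is therefore relative to the bulk of the RNA on its array. The files used here carry no gene name column, so probes were named through their RefSeq accession in the NCBI gene table (assembly GRCh38.p14, used for names only). Of 29854 probes with an mRNA or noncoding RNA accession, 28984 matched, and in all 29033 probes were named, for 20992 gene symbols. The other 21566 probes have no name here. They enter the 75th percentile of each array, 1 alternative and a count of their own in the closing section, and none of the gene values. A gene was represented by its brightest probe over the 4 arrays, and the second-brightest probe was looked at where it was measured.

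Signal over background takes the place of depth. Between 50.9% (SK-MES-1 at 50% O2) and 54.2% (SK-MES-1 at 20% O2) of probes were well above background by the scanner's flag. In a line, a gene was compared when its probe was well above background on both arrays. A gene below background on 1 of them has only a bound, computed as the brighter signal over the higher of the dim signal and the lowest signal well above background on that array. On each array 902 probes have 10 spots, and the median SD of log2 signal over such spots was between 0.0600 and 0.0684 for detected probes. The errors given with log2 differences (±) come from the scanner software's error model, divided by the square root of the number of spots. For 1 bright spot per array the error of a difference is 0.20, which holds wherever no other error is printed. These errors cover the measurement on the array and not the spread between cultures.

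With 1 array per group no test within a line is possible, and differences at 50% against 20% O2 are given as log2 values with counts of genes at least 2-fold higher or lower. The oxygen difference shared by the lines and the difference between the lines were fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) on all 4 arrays, with cell line and oxygen level as terms, for genes well above background on at least 2 arrays, at a Benjamini-Hochberg adjusted p of 0.05. This fit has 1 residual degree of freedom, made only of the lines' disagreement about oxygen. Its p-values measure only the spread between these arrays, since nothing states that further cultures exist. The limma fit was tested on simulated data for 15519 genes. For the oxygen difference it recovered 6% of genes changed by 1 log2 unit, 66% by 2 and 92% by 3, with 6 false calls. For the line difference it recovered 0% of genes changed by 1 log2 unit, 86% by 2 and 96% by 4, with 7 false calls. In each simulation 50 genes were changed at each size. On the real arrays 50.3% of genes were called between the lines, and more true differences make the adjusted threshold less strict. The simulated recovery, 0% at 1 log2 unit included, therefore does not describe the real line comparison. For the oxygen difference the simulated changes were identical in both lines, whereas on the real arrays 0 genes were called. With fewer true shared differences the adjusted threshold is stricter, so the simulated recovery can overstate that of the real oxygen comparison.

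For 38 gene lists written before the data were examined, the median log2 difference of measured members was set against 10000 random lists of the same size matched on mean signal in 20 bins. Its percentile describes these arrays and is not a test, and the random range means the 2.5 to 97.5 percentile. Lists outside it in either line are described, as are 6 lists regardless of result, and the others are given together. Named genes follow a rule fixed at the same time. It takes per line the 12 genes with the largest difference each way, the 12 with the largest smaller-of-both-lines difference each way, 6 each way for the difference in response, 12 each way for the line difference, up to 4 detected members of each list by mean absolute difference, a short fixed set of hypoxia, oxidative stress and growth genes, tissue markers, and 3 bounds each way per line. Names made of an accession, clone or locus identifier, Y-linked genes and XIST were passed over. A few genes that the rule names are not reported here. Members of near-identical families (AKR1C, metallothionein, HSPA1, histone, MAGEA, CT45A and SPANX genes, and pseudogenes) can share probe signal, and their values are uncertain in that sense.

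Alternatives were normexp background correction (offset 50), quantile normalization, a shift by the median of detected probes, the rounded deposited table, no filter and a stricter filter on dim probes, the mean of a gene's probes, fold thresholds of 1.5 and 3, variance models and terms of the limma fit, an adjusted p of 0.1, and other forms of the list comparison. Normexp had been planned on mean spot brightness, and the median brightness was used because the mean is not among the columns of the files used here. All probes, a signal minimum of 100, scaling to spike-in controls and the ATF4 list without its HIF targets were added after seeing the data.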

Results

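The series compared gene expression of lung cancer cells after 24 h in 50% O2 with that in 20% O2, the level of an ordinary incubator. H1975 is an established human lung adenocarcinoma line with a mutated epidermal growth factor receptor, and SK-MES-1 is an established human lung squamous carcinoma line. Each of the 4 combinations of line and oxygen level was measured on 1 array. There are no replicates, so no difference within a line has a replicate check, and differences are described as higher or lower at 50% O2 on the log2 scale. The number of arrays limits the precision. Of the named genes, 14551 were measured on both H1975 arrays, 14455 on both SK-MES-1 arrays and 13629 on all 4.

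The differences are relative to the bulk of each array. The Agilent spike-in RNAs, of which 8 were measured, had a median difference of -0.47 in H1975 and 0.59 in SK-MES-1 between 50% and 20% O2 after the 75th percentile was subtracted. Scaled to them, a choice made after seeing the data, every gene shifts by the opposite amount, and the counts at least 2-fold higher and lower were 277 and 6 in H1975 (26 and 23 without it) and 49 and 1250 in SK-MES-1 (166 and 68 without it). The position of a list among the other genes of its array is unaffected.

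In H1975, targets of NRF2 and ATF4 were higher at 50% O2, and genes of the hypoxia programme were lower, relative to the other genes of the array. Targets of NRF2, the transcription factor that induces detoxifying and antioxidant genes, had a median difference of 0.28 (percentile 100 of matched random lists), with 26 of 28 above 0, 5 at least 1.5-fold higher and 0 as much lower. Among them AKR1C1, an aldo-keto reductase, was higher by 1.59 ± 0.34 (second probe 0.92), the cystine transporter gene SLC7A11 by 1.33, AKR1C3 by 1.32 and the haem oxygenase gene HMOX1 by 1.12 ± 0.06. NQO1 (0.26) and TXNRD1 (0.35), which belong to the same programme, differed less. Targets of ATF4, the transcription factor of the amino acid response, had a median of 0.39 (percentile 100), with 24 of 28 above 0 and 7 at least 1.5-fold higher. They included SLC7A11 again, the glutathione-degrading enzyme gene CHAC1 (0.95), the asparagine synthetase gene ASNS (0.91) and ATF3 (0.57; other probes 0.07 to 0.57). GDF15, a stress-induced secreted factor, was higher by 1.36.

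Targets of the hypoxia-inducible factors (HIF) had a median of -0.28 in H1975 (percentile 0), with 37 of 39 below 0, 5 of them at least 1.5-fold lower and 0 at least 2-fold lower; scaled to the spike-in RNAs, a choice made after seeing the data, the median was 0.19. ANGPTL4 had a difference of -0.87, the carbonic anhydrase gene CA9 -0.84, NDRG1 -0.73 and ADM -0.67 ± 0.06. HILPDA stood at -0.57. The glucose transporter gene SLC2A1 (-0.24) and VEGFA (0.03, second probe -0.25) differed less. Glycolysis enzymes, a list that shares SLC2A1, PFKFB3 and PDK1 with the HIF targets, had a median of -0.23 (percentile 0; 0.24 scaled to the spike-ins) with 19 of 22 below 0, for example ENO2 (-0.42), HK2 (-0.41), PDK1 (-0.35) and PFKFB3 (-0.13), and PGK1 had -0.36 ± 0.06.

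Other lists stood apart from random lists in H1975 with smaller medians. NF-kB and inflammatory genes had 0.18 (percentile 99.99, 18 of 22 above 0), with CXCL8 at 0.51 and IL11 at 0.32. Drug efflux pumps had 0.40 (percentile 99.9, 5 of 5 above 0), with ABCC2 at 0.66 ± 0.24 and ABCC5 at 0.40 (other probes 0.04 and 0.52), but 0.16 with normexp (percentile 96.6), inside the random range. That list shares ABCC2 and ABCC3 with the NRF2 targets. Immediate-early and MAPK feedback genes had 0.12 (percentile 97.8), with DUSP5 at 0.60 ± 0.21, and lay inside the range under 3 alternatives (percentile 95.6 with the mean of probes). DNA repair genes had 0.11 (percentile 98.1, 32 of 37 above 0), with NEIL1 at 0.41 ± 0.21. The medians below 0 that follow were above 0 when scaled to the spike-ins. Replication-dependent histone genes had -0.19 (percentile 0, 14 of 15 below 0), with H4C8 at -0.27. G2/M genes had -0.072 (percentile 0, 23 of 31 below 0), with CDCA3 at -0.30 and KIF20A at -0.27 ± 0.06. TGF-beta targets had -0.11 (percentile 0.32), with COL1A1 at -0.55, and mesenchymal genes -0.13 (percentile 2.01, 7 of 10 below 0), with SNAI1 at -0.21 and ZEB2 at -0.33 ± 0.32 (second probe 0.22). The mesenchymal list lay inside the range under 5 alternatives, at the least -0.059 (percentile 12.9). The short-lived transcripts held as a sign of RNA quality and handling had 0.088 (percentile 86.8).

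Of the 14551 genes measured in H1975, 26 were at least 2-fold higher at 50% O2 and 23 at least 2-fold lower. The 12 largest positive differences included those of AKR1C1, SLC7A11, AKR1C3 and GDF15, given above. The others were those of ARHGEF38 (3.94 ± 0.35), PTPRVP (3.92 ± 0.27), SEC24B-AS1 (1.56 ± 0.22), SHC2 (1.45 ± 0.25), NHSL1 (1.37 ± 0.34), OLAH (1.27 ± 0.36), SLC16A14 (1.24 ± 0.23) and SPON2 (1.19 ± 0.14). The 12 largest negative differences were those of EPB41L4A (-2.28 ± 0.35), FXYD2 (-2.09 ± 0.24), the pseudogene SLC22A20P (-1.92 ± 0.32), ZIC2 (-1.61 ± 0.22), KCNK3 (-1.61 ± 0.35), LOXL4 (-1.36 ± 0.32), DYTN (-1.33), the calprotectin subunit gene S100A8 (-1.32 ± 0.21), TAS2R60 (-1.22 ± 0.34), SH3PXD2A-AS1 (-1.20 ± 0.25), EFCAB3 (-1.18 ± 0.21) and DEPP1 (-1.15). Most of these genes were dim. With a signal of at least 100 on both arrays, a limit chosen after seeing the data, 5 genes were at least 2-fold higher and 5 lower. A second probe was measured for 3 of the 49 genes, had the same sign in 3 and was at least 2-fold different in 0. For others, ARHGEF38, EPB41L4A and FXYD2 among them, a second probe was present but not measured on both arrays of the line. EGFR had 0.64 on its brightest probe and 0.20 and 0.04 on its others. CDKN1A had -0.37 ± 0.23, CYP1A1 -0.50 ± 0.23, MKI67 -0.11 (other probes -0.38 and -0.24) and SOD2 0.10. A further 346 genes were well above background only at 50% O2 and 293 only at 20% O2, with a bound of at least 2-fold for 27 and 33 of them. The largest bounds were at least 11.04-fold higher at 50% O2 for C2CD4B, 9.42-fold for BTN1A1 and 5.07-fold for DPY19L2P2, and at least 11.1-fold higher at 20% O2 for SERPINA9, 8.11-fold for NIPAL2 and 8.01-fold for CMA1.

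In SK-MES-1 the hypoxia programme was higher at 50% O2. HIF targets had a median of 1.12 (percentile 100; 0.53 scaled to the spike-ins), with 39 of 39 above 0 and 22 at least 2-fold higher. ADM was higher by 3.03 ± 0.06, ANGPTL4 by 2.93, HILPDA by 2.56, NDRG1 by 2.22, CA9 by 2.01 ± 0.25, VEGFA by 1.04 and SLC2A1 by 0.995. Glycolysis enzymes had a median of 0.20 (percentile 100; -0.39 scaled to the spike-ins) with 15 of 20 above 0 and 4 at least 2-fold higher, namely PFKFB3 (1.93), ENO2 (1.76), PDK1 (1.40) and HK2 (1.33). PFKFB3 and PDK1 are also in the HIF list, so the 2 lists are not separate. The lower quartile was 0.024, and 1 enzyme, PFKL (-0.71), was at least 1.5-fold lower. The second probes of PFKFB3 (0.85) and HK2 (0.60) gave smaller differences.

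ATF4 targets, immediate-early genes and heat shock genes were higher as well in SK-MES-1 at 50% O2 relative to the other genes of the array, whereas endoplasmic reticulum chaperones had a median of -0.14, inside the random range (percentile 4.03, 13 of 18 below 0). Scaled to the spike-ins, the medians of the lists in this paragraph were below 0 except that of the short-lived transcripts. ATF4 targets had a median of 0.55 (percentile 100), with 26 of 28 above 0 and 5 at least 2-fold higher. The list shares 3 genes with the HIF targets, DDIT4 (1.40 ± 0.06), VLDLR (1.25, second probe 0.70) and STC2 (0.66), named because of this overlap and after their values were seen. Without them, an alternative chosen after seeing the data, its median was 0.49 (percentile 100), with 23 of 25 above 0 and 3 at least 2-fold higher, and in H1975 it was 0.44 (percentile 100), with 24 of 25 above 0. In SK-MES-1 ATF3 was among the latter (2.31; other probes 0.36 to 2.40), as was CHAC1 (1.101), and ASNS stood at 0.66. Immediate-early and MAPK feedback genes had 0.39 (percentile 100, 17 of 20 above 0), led by FOS (4.32 ± 0.25), EGR1 (3.98 ± 0.21), DUSP1 (2.46 ± 0.06) and DUSP5 (1.20). The short-lived transcripts that mark RNA quality and handling, a list that shares FOS, EGR1, DUSP1 and ATF3, among others, with those lists, had a median of 0.66 (percentile 100) with 16 of 16 above 0. Heat shock genes had 0.36 (percentile 100, 12 of 14 above 0), with HSPA6 at 2.04, HSPA1B at 1.099 and HSPA1A at 0.95 ± 0.06. Apoptosis regulators had 0.13 (percentile 99.6), with PMAIP1 at 0.72 and BCL2L11 at 0.70 ± 0.21 (other probes 0.31 and -0.22). NF-kB and inflammatory genes had 0.087 (percentile 98.0), with CSF2 at 1.28 and PTGS2 at 1.26 ± 0.08. NRF2 targets had 0.058 (percentile 98.2), with 15 of 28 above 0. HMOX1 was higher by 2.31 ± 0.06 and TXNRD1 by 0.34, much as in H1975 (0.35), and SLC7A11 (0.21), AKR1C1 (0.04), AKR1C3 (-0.20) and NQO1 (-0.02) lay near 0. The percentiles of the NRF2 and NF-kB lists in this line lay inside the random range under 5 alternatives each.

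Several lists were lower in SK-MES-1 at 50% O2. Genes of ribosome biogenesis and MYC targets had a median of -0.26 (percentile 0.01, 17 of 20 below 0), with BOP1 at -0.64 and RRP9 at -0.53. S phase genes had -0.22 (percentile 0.02, 25 of 30 below 0), with MCM7 at -0.59 and CCNE2 at -0.48 ± 0.21 (second probe -0.24). G2/M genes lay inside the random range at -0.12 (percentile 6.20, 23 of 31 below 0), with CDC20 at -0.62 and PLK1 at -0.59. Cholesterol synthesis genes had -0.23 (percentile 0.08, 21 of 24 below 0), with SREBF2 at -0.62. Fatty acid synthesis genes had -0.22 (percentile 2.21), with FASN at -0.83, and lay inside the range under 3 alternatives (-0.17 with normexp, percentile 3.65). Interferon-stimulated genes had -0.22 (percentile 0.08, 21 of 26 below 0), with DDX60 at -0.73 ± 0.21 and OASL at -0.67. Metallothionein genes, which bind zinc and copper, had -0.68 (percentile 0, 8 of 8 below 0), with MT1M at -1.07, MT1E at -0.81 and MT1X at -0.75 (second probe -0.26).

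Of the 14455 genes measured in SK-MES-1, 166 were at least 2-fold higher at 50% O2 and 68 at least 2-fold lower. The 12 largest positive differences included those of FOS, EGR1, ADM and ANGPTL4, given above. The others were those of CASZ1 (4.84 ± 0.23), MOV10L1 (3.60 ± 0.34), SPANXN2 (3.23 ± 0.34), SNORA38B (2.98 ± 0.30), CIMAP1A (2.91 ± 0.24), TRIM62 (2.90 ± 0.34), TCAF2 (2.81 ± 0.21) and RIMKLA (2.80 ± 0.22). The second probe of TRIM62 gave 0.49. The 12 largest negative differences were those of the parvalbumin gene PVALB (-5.06 ± 0.31), LSM11 (-2.16 ± 0.25), PDE4C (-1.95 ± 0.25), DENND2A (-1.82 ± 0.26), TSNAXIP1 (-1.80 ± 0.31), MTM1 (-1.80 ± 0.27), CDC73 (-1.77 ± 0.21), KRT31 (-1.75 ± 0.22), CTDSP1 (-1.65), TMEM129 (-1.61 ± 0.21), APBA1 (-1.54 ± 0.34) and ACAD8 (-1.51 ± 0.23). The second probe of CTDSP1 gave -0.93. Over the 234 genes, a second probe was measured for 42, had the same sign in 41 and was at least 2-fold different the same way in 14. For others, CASZ1, MOV10L1, CIMAP1A and TCAF2 among them, a second probe was present but not measured on both arrays of the line. With a signal of at least 100 on both arrays, 88 genes were at least 2-fold higher and 30 lower. CDKN1A was higher by 0.83 ± 0.21, MKI67 had -0.34 (other probes -0.77 and -0.31), CYP1A1 -0.51 ± 0.24, SOD2 -0.16 and EGFR 0.05. A further 175 genes were well above background only at 50% O2 and 703 only at 20% O2. The bound was at least 2-fold for 92 and 74 of them. The lowest log2 signal well above background was 4.18 on the 50% O2 array and 3.90 on the 20% O2 array. The numbers 175 and 703 therefore do not show a direction of change. The largest bounds were at least 40.1-fold higher at 50% O2 for LGALS12, 34.3-fold for OR2A12 and 26.1-fold for C1orf146, and at least 27.2-fold higher at 20% O2 for ERVW-1, 24.0-fold for OR52E4 and 23.3-fold for MEDAG.

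**Figure D1:**
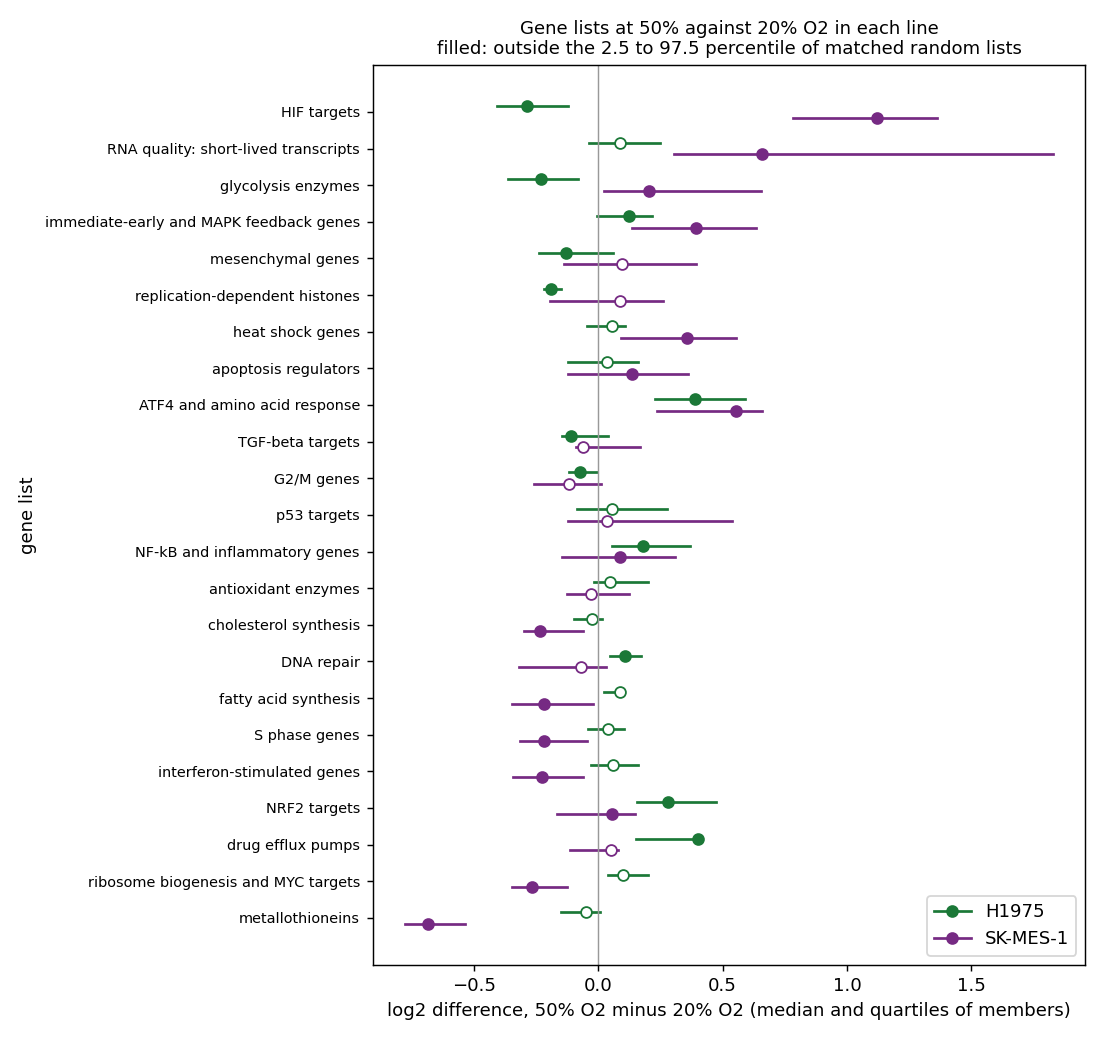
Median log2 difference between 50% and 20% O2 (x axis) of 23 gene lists (y axis) in H1975 and SK-MES-1, 1 array per line and oxygen level; bars span the quartiles of a list's measured members, and filled points lie outside the range of matched random lists. HIF targets lie at -0.28 in H1975 and 1.12 in SK-MES-1 (0.19 and 0.53 scaled to the spike-ins), and ATF4 targets at 0.39 and 0.55 (0.86 and -0.036).

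The antioxidant enzyme list stayed near random lists in both lines, with medians of 0.046 (percentile 63.0) in H1975 and -0.030 (percentile 60.6) in SK-MES-1, although SESN2 was higher by 0.86 ± 0.21 in H1975 and by 0.59 in SK-MES-1, and GLRX by 0.95 in SK-MES-1. The p53 target list had medians of 0.057 (percentile 73.1) and 0.034 (percentile 85.1), with TP53INP1 at -0.23 ± 0.25 and 1.16 ± 0.30. The 15 lists given together, which include ribosomal proteins, respiratory chain, endoplasmic reticulum chaperones, extracellular matrix, AHR targets, housekeeping genes and the markers of adenocarcinoma, squamous carcinoma, leukocytes, endothelium and fibroblasts, had medians from -0.30 to 0.13 in H1975 and from -0.26 to 0.074 in SK-MES-1. All were inside the random range in the main setting, which need not hold under the alternatives. In all, 12 of 38 lists lay outside the random range in H1975 and 15 in SK-MES-1. By chance 1.9 per line would, if the members of a list varied independently as in the random draws. Members that vary together put more lists outside without any effect of oxygen, so these counts do not test oxygen.

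Among the 13629 genes measured on all 4 arrays, 22 were at least 2-fold higher in H1975, 140 in SK-MES-1 and 4 in both. The genes at least 2-fold higher at 50% O2 in both were GDF15 (1.36 in H1975 and 1.40 in SK-MES-1), the hedgehog ligand gene SHH (1.16 ± 0.26 and 1.94 ± 0.30), HMOX1 (1.12 ± 0.06 and 2.31 ± 0.06) and the interleukin-6 receptor gene IL6R (1.01 ± 0.34 and 1.32 ± 0.25), whose second probe gave 0.17 and 0.53. CHAC1 (0.95 and 1.101) followed, then NEO1 (1.18 ± 0.35 and 0.92 ± 0.38), ECM2 (0.94 ± 0.23 and 0.91 ± 0.24), RFX8 (0.82 ± 0.21 and 1.16 ± 0.21), OR5V1 (0.79 ± 0.22 and 0.999 ± 0.22), TUSC1 (0.77 and 0.99) and FAM209A (0.71 ± 0.22 and 0.95 ± 0.34). Of these shared genes, SHH (signal 27 to 103 over the 4 arrays), IL6R (20 to 94), NEO1 (17 to 38), ECM2, OR5V1 and FAM209A were dim, with a signal under 100 on at least 1 array. Other probes did not share the difference of TUSC1 (-0.05 and -0.25) or, in H1975, that of RFX8 (-0.07, and -0.11 to 0.66 in SK-MES-1), while that of CHAC1 gave 1.20 and 0.82. No gene (0) was at least 2-fold lower in both. The 12 largest shared negative differences included PTPN22 (-0.88 ± 0.32 and -1.41 ± 0.31) and the phosphofructokinase gene PFKL (-0.74 and -0.71), with RNASE13, KBTBD3, HYAL1, NCAPH, ACTG1P4, SLC22A20P, KRT31, IQCC and TPBGL between -0.61 and -1.92 in either line. ATF4, NRF2, NF-kB and immediate-early lists were the 4 lists outside the range in the same direction in both lines. Of these, NRF2 and NF-kB genes in SK-MES-1 and immediate-early genes in H1975 lay inside it under some alternatives and ATF4 targets under none, and scaled to the spike-ins all 4 medians in SK-MES-1 were below 0. In the limma fit across both lines 0 of 15519 genes were higher and 0 lower at 50% O2 after Benjamini-Hochberg adjustment (smallest adjusted p 0.913), and 649 had an unadjusted p under 0.05 where chance gives 776. Adjusted over the list alone, 1 gene was called, GDF15 in the p53 target list. With normexp background correction the fit called GDF15 (limma adjusted p 0.00194), HMOX1 (0.0216), CHAC1 (0.0233) and TUSC1 (0.0452, on the probe that its other probe does not bear out), all higher, and had 935 genes with an unadjusted p under 0.05.

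Relative to each array's 75th percentile, the hypoxia programme was lower at 50% O2 in H1975 and higher in SK-MES-1. The difference of the 2 lines' changes (SK-MES-1 minus H1975) had a median of 1.32 over the 39 HIF targets (0.26 scaled to the spike-ins) and 0.37 over the 20 glycolysis enzymes measured in both, which turned to -0.70 with that scaling. The short-lived transcripts that mark RNA quality and handling had 0.69 (percentile 100; -0.37 scaled to the spike-ins), and metallothioneins had -0.66 (percentile 0; -1.72 scaled to the spike-ins). HIF targets and glycolysis enzymes were the 2 lists outside the random range in opposite directions, although scaled to the spike-ins HIF targets had medians above 0 in both lines. Among 13629 genes, 31 had a change at least 4-fold more positive in SK-MES-1 and 2 at least 4-fold more negative, PVALB and PDE4C. Scaled to the spike-ins these counts were 9 and 184. CASZ1, FOS, DEPP1, ANGPTL4, SNORA38B and ADM led the first group. The most negative after PVALB and PDE4C were TSNAXIP1, TMEM129, CLDND2 (0.28 ± 0.43 in H1975 and -1.47 ± 0.28 in SK-MES-1) and SFXN2 (0.38 ± 0.23 and -1.34 ± 0.22). DEPP1 (-1.15 and 2.75) and EFCAB3 (-1.18 ± 0.21 and 1.23 ± 0.33) were the 2 genes at least 2-fold different in opposite directions, both lower in H1975 and higher in SK-MES-1. Scaled to the spike-ins, 18 genes differed in opposite directions. Across genes, which are not independent replicates, the changes of the lines had a Pearson r of 0.048 and a Spearman rho of 0.083. The difference between the lines in response could not be tested with 1 array per group.

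**Figure D2:**
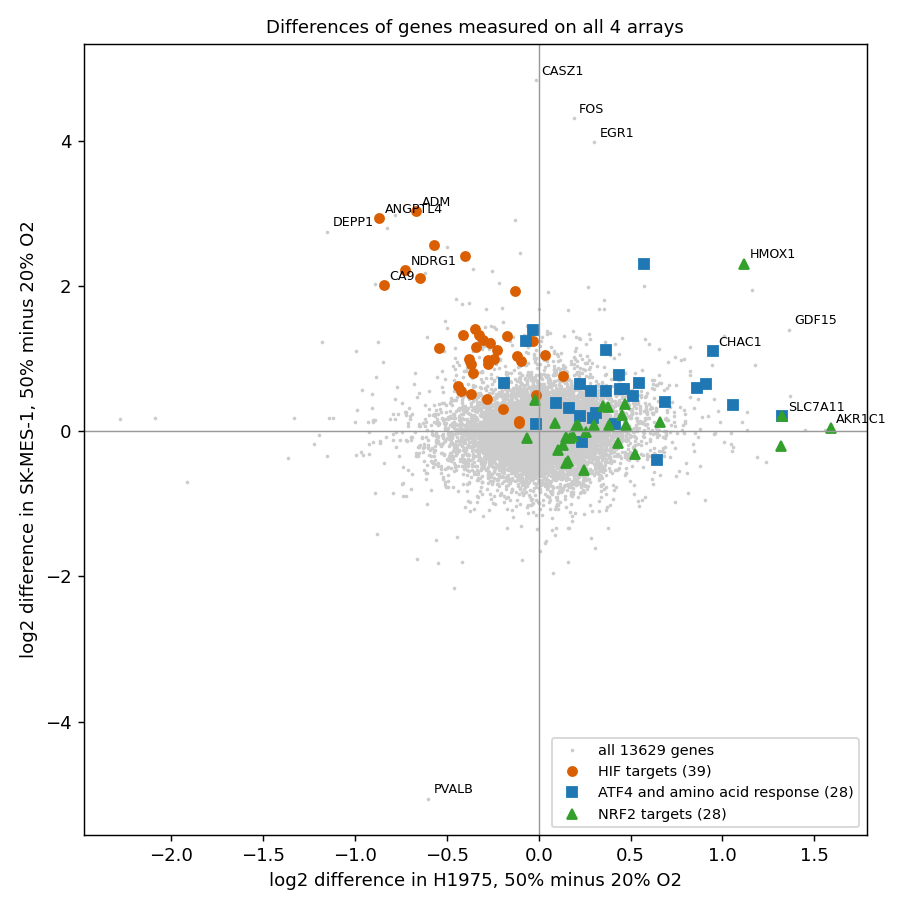
Log2 difference between 50% and 20% O2 in H1975 (x axis) against that in SK-MES-1 (y axis) for the 13629 genes measured on all 4 arrays, 1 point per gene; coloured points are members of the HIF (39), ATF4 (28) and NRF2 (28) lists. Relative to each array's 75th percentile, HIF targets lie above 0 in SK-MES-1 and mostly below 0 in H1975 (above 0 in both by median when scaled to the spike-ins), and HMOX1, GDF15 and CHAC1 lie above 0 in both.

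Between the lines, independently of oxygen, 3664 genes were higher in SK-MES-1 and 4145 higher in H1975 (limma, Benjamini-Hochberg adjusted p under 0.05, 15519 genes). NRF2 targets were higher in SK-MES-1, with a median log2 difference of 1.89 over 28 genes, 22 called higher, 0 called lower and 23 called when adjusted over the list alone. AKR1C1 differed by 9.84 ± 0.42 (SE, limma adjusted p 0.000861). Epithelial junction genes were lower in SK-MES-1, with a median of -2.19 over 19 genes, 16 called higher in H1975 and 2 in SK-MES-1 (18 adjusted over the list alone). Interferon-stimulated genes had a median of -0.66, with 17 of 28 called higher in H1975 and 3 in SK-MES-1 (20 adjusted over the list alone), and replication-dependent histones -0.76, with 12 of 15 called higher in H1975 (12 adjusted over the list alone).

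The largest differences between the lines were mostly those of genes not well above background in 1 line, and cancer-testis genes were among them in both directions. In SK-MES-1, MAGEA2B was at least 2658-fold higher, SPANXA1 at least 1968-fold, BEX3 at least 1760-fold, MAGEA12 at least 856-fold and NR0B1 at least 763-fold. GALNT14, SPP1 (osteopontin), TSPYL5, STK24 and PGAP4 were at least 513-fold, 455-fold, 395-fold, 368-fold and 267-fold higher, and the matrix protease gene MMP7, measured on 1 of 2 H1975 arrays, differed by 9.79 ± 0.29 (SE). In H1975, the noncoding RNA gene UCA1 was at least 1709-fold higher, the tetherin gene BST2 at least 1302-fold, CT45A5 at least 865-fold, IFITM1 at least 558-fold, PEG10 at least 252-fold, NTN1 at least 249-fold, MB at least 214-fold, CT83 at least 171-fold and ADAMTS9 at least 138-fold, while CT45A1, measured on 1 of 2 SK-MES-1 arrays, DHRS2 and SNAR-G1 differed by -10.32 ± 0.27, -10.19 ± 0.16 and -10.13 ± 0.14 (SE). With AKR1C1, these are 24 genes, whose limma adjusted p was between 0.000368 and 0.000861. Where they had a second probe it had the same sign. For genes below background in 1 line, here and among the tissue markers below, the fit used the measured signals and not the bounds. Their p-values and SE therefore leave out the uncertainty of those dim signals.

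Tissue markers separated the lines in part. The lung lineage factor gene NKX2-1 was at least 70.1-fold higher in H1975 (limma adjusted p 0.000383), and MUC1 8.01-fold higher (adjusted p 0.000911). KRT7 was 1.80-fold higher in H1975 (adjusted p 0.0125). Among squamous markers, S100A2 was 24.7-fold higher (adjusted p 0.000482) and PKP1 at least 19.6-fold higher in SK-MES-1, and KRT15 2.54-fold higher there, whereas KRT14 was at least 29.3-fold higher in H1975 and CALML3 3.68-fold higher there. KRT5, KRT6A, KRT6B, DSG3 and DSC3 were not well above background on any array, and TP63 was so on 1 SK-MES-1 array only. By list, 7 of 13 measured squamous markers were called higher in H1975 and 5 in SK-MES-1 (12 adjusted over the list alone), and 4 of 7 adenocarcinoma markers were called higher in H1975 and 1 in SK-MES-1 (6 adjusted over the list alone).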

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

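The tests of exchanged labels and of culture handling and the scaling to spike-ins were chosen only after the results they use were seen, and the reading of the test of single spots was revised after its result. All differences here are between single arrays, and none of the differences between the lines was tested.

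Relative to the other genes of each array, the response of the hypoxia programme went opposite ways in the lines. The median difference of the lines' changes, SK-MES-1 minus H1975, was 1.32 for HIF targets (0.26 scaled to the spike-ins) and 0.37 for glycolysis enzymes (-0.70, the sign turned), and among single genes it was 3.90 for DEPP1 and 2.41 for EFCAB3. Normexp and quantile normalization were the settings tried that can move a list against all genes. With them the HIF list stayed at least 0.24 below the median of all genes in H1975 (highest value -0.24). In SK-MES-1 it stayed at least 1.046 above that median. In the main setting the list lay at -0.32 and 1.14 against all genes, so both settings moved it little. They show only that the choice among these settings does not make the list stand apart, and cannot exclude other effects of scaling or background correction. The sign itself depends on scaling, since scaled to the spike-ins the medians were 0.19 in H1975 and 0.53 in SK-MES-1. Exchanged labels of the SK-MES-1 arrays stay open. Of the 6 lists outside the random range in both lines, 4 went the same way as labelled and 2 opposite ways, and since the lines need not respond alike this count cannot exclude an exchange. A difference in culture state or handling of the SK-MES-1 culture at 50% O2 stays open too: short-lived transcripts had a median of 0.66 there, and with 1 culture this cannot be told apart from an effect of oxygen. A biological difference between the lines remains a further, untested explanation.

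A signal was also seen in probes that have no gene name here. Relative to the 20% O2 array, 109 such probes were at least 2-fold higher at 50% O2 in SK-MES-1 and 25 in H1975, against 38 and 16 at least 2-fold lower, among 5906 and 6198 measured.

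Very large differences of dim genes form a separate pattern. Among genes on 1 spot with a signal under 100 on the dimmer array, 4 in H1975 and 20 in SK-MES-1 differed at least 4-fold. Among the replicate spots of dim probes, 8 of 1930 on the H1975 arrays and 6 of 2090 on the SK-MES-1 arrays lay at least 4-fold off their probe's median, which would give 24.2 such genes (95% exact binomial range 10.5 to 47.7) and 16.6 (6.08 to 36.0). By the criterion set before the result, a rate giving at least 50% of the observed number, deviating spots would have counted as the cause in both lines. That criterion was wrong: the rate overstates the number in H1975, even at the low end of its range, and so decides neither line. Spots with an outlier flag were kept for the rate, whereas the gene values left them out. Why the rate overstates the number was not tested. Single deviating spots therefore stay open as an explanation for dim genes such as CASZ1, PVALB, ARHGEF38 and PTPRVP, and no biological explanation was tested for these.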

How the results depend on the processing

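The alternatives were listed before the data were examined, except all probes, the signal minimum of 100, spike-in scaling and the ATF4 list without its HIF targets, chosen after seeing the data. Signal over background limits the counts in H1975, where most genes at least 2-fold different were dim, and spike-in scaling moved the number lower in SK-MES-1 most. The cause of the changes below was not tested except where the alternative's construction gives it. Counts are in the order H1975 higher and lower, SK-MES-1 higher and lower (26, 23, 166 and 68 in the main setting), both lines higher and lower (4 and 0), change at least 4-fold more positive and more negative in SK-MES-1 (31 and 2), and opposite directions (2). Normexp, whose offset shrinks dim differences by construction, gave 6, 4, 83 and 22, then 2 higher in both lines, 16 and 1, and 1 opposite, with 4 shared oxygen calls where the main setting had 0. With no filter on dim probes they were 606, 545, 643 and 580, 59 and 48, 251 and 217, and 76. Requiring all 4 arrays left 12 genes lower in H1975. At 1.5-fold (2-fold for the difference of changes) they were 204, 198, 598 and 509, 31 and 14, 191 and 132, and 26, and at 3-fold (8-fold) 3, 5, 49 and 10, 0 higher in both lines, 11 and 1, and 0. All probes gave 63, 41, 317 and 139, and a signal of at least 100 gave 5, 5, 88 and 30. Spike-in scaling gave 277, 6, 49 and 1250, 1 lower in both lines, 9 and 184, and 18 opposite. Within other settings these counts stayed within 1.5 times.

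Spike-in scaling adds a constant per line, so percentiles stand by construction, but it turned the sign of 13 medians. In H1975, HIF targets then had 0.19, glycolysis 0.24, G2/M 0.40, histones 0.28, mesenchymal 0.34 and TGF-beta genes 0.36. In SK-MES-1, glycolysis had -0.39, NRF2 -0.53, ATF4 -0.036, heat shock -0.23, NF-kB -0.50, immediate-early -0.20 and apoptosis genes -0.46. The medians of the difference of changes became 0.26 for HIF targets, -0.70 for glycolysis, -0.37 for short-lived transcripts (both above 0 without it) and -1.72 for metallothioneins.

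Some list medians moved inside the random range with the same sign. In SK-MES-1, NRF2 targets did with normexp (0.045), quantile normalization (0.065), the mean of probes (0.029), unmatched random lists (0.058) and the mean over members detected on all 4 arrays (0.074); NF-kB genes with quantile normalization (0.084), no filter (0.055), the 4-array filter (0.055), unmatched lists (0.087) and the mean over members (0.094); and fatty acid synthesis with normexp (-0.17), no filter (-0.18) and the mean of probes (-0.20). In H1975, drug efflux pumps did with normexp (0.16), mesenchymal genes with quantile normalization (-0.11), no filter (-0.091), the 4-array filter (-0.12), the mean of probes (-0.061) and the mean over members (-0.059), and immediate-early genes with the mean of probes (0.10), unmatched lists (0.12) and the mean over members (0.12). The other 237 list values outside the range stayed outside with their sign. For lists inside the range in the main setting, alternatives moved 22 values outside it with the same sign and turned the sign of 34, while 385 did neither. Without the spike-in scaling, and with all list members, HIF targets ranged from -0.31 to -0.23 in H1975 and from 0.995 to 1.22 in SK-MES-1, and ATF4 targets from 0.35 to 0.43 and from 0.55 to 0.57 (0.44 and 0.49 without the genes shared with the HIF list).

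The limma calls between the lines ranged from 2819 to 4475 higher in SK-MES-1 and from 3141 to 4934 higher in H1975, and 7674 of 7809 calls were shared with quantile normalization. Leaving out 1 array leaves no residual degree of freedom. The genes at least 2-fold higher then numbered 2238 to 2258 in SK-MES-1 (2152 with all arrays) and 2313 to 2608 in H1975 (2399). Leaving out a line leaves only the values per line. Of the named genes' values, 676 moved by less than their array error and 94 by more, over 5 scalings, background corrections and probe rules, and 0 of those at least 2-fold different changed sign. No paired analysis was possible because each group holds 1 array, so replicate numbers pair nothing; the limma fit already compares oxygen within lines through its term for cell line, on 1 residual degree of freedom.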

Other observations

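Of the tests here, the one on NRF2 targets was chosen only after its result was seen: it was rewritten once a first correlation was known. The spike-in scaling was also chosen after seeing the data. The iron import receptor gene TFRC was higher in H1975 by 0.68 ± 0.06 on a 10-spot probe and differed by 0.01 ± 0.06 in SK-MES-1.

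ATF4 targets were higher at 50% O2 in both lines relative to the other genes of each array, while scaled to the spike-ins their medians were 0.86 in H1975 and -0.036 in SK-MES-1 (0.91 and -0.10 without the 3 genes shared with the HIF list). With normexp and with quantile normalization, and in both lines, the list stayed at least 0.345 above the median of all genes. These settings moved the list little against the main setting, where it lay 0.36 above that median in H1975 and 0.57 in SK-MES-1. They show only that the choice among these settings does not make the list stand apart, and cannot exclude other effects of scaling or background correction. A second list of amino acid response genes, with no gene in common with the first, 1 in common with the HIF list and written before its values were seen, had a median of 0.25 in H1975, with 27 of 27 above 0, and 0.25 in SK-MES-1, with 25 of 27 above 0, but 0.72 and -0.34 scaled to the spike-ins. Its percentile among matched random lists was 100 in the line where it was lower. This is consistent, as a hypothesis, with an amino acid response relative to the other genes of each array in both lines, whose direction in SK-MES-1 depends on the scaling. Differences in medium use or culture density between the 20% and 50% O2 cultures were not tested, and with 1 culture per group they remain open.

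NRF2 targets differed by a median of 0.28 in H1975 and 0.058 in SK-MES-1, and started higher in SK-MES-1, by a median of 1.99 at 20% O2 (26 of 28 genes). A candidate explanation is that the programme was already high in SK-MES-1. Across these 28 genes, which are not independent replicates, the H1975 difference went with that starting gap (Spearman rho 0.52, above 98.2% of random gene sets). The 2 measures share the H1975 array at 20% O2, which adds a positive correlation by chance. With the gap taken against H1975 at 50% O2, which biases the other way, rho was 0.40 (above 99.4% of random sets) and Pearson's r 0.62. Without the 2 genes farthest from the median, rho was 0.40 against the array at 20% O2 and 0.26 against that at 50% O2, and r was 0.39 and 0.14. The relation is weaker without those genes, r more than rho. The SK-MES-1 array at 50% O2 does not enter these correlations. They therefore do not test whether a high start limited the difference in SK-MES-1. HMOX1 started higher in SK-MES-1 (signal 53128 against 12701 at 20% O2) and yet differed more there (2.31 against 1.12). AKR1C1, AKR1C3 and SLC7A11 also started higher in SK-MES-1 and differed more in H1975. The question stays open.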
